A study of Mus musculus with 9 samples.

How the data were processed

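Total RNA of hippocampal tissue from 9 mouse samples was sequenced, 3 each labelled young control, old sham and old hpMSC-treated. The deposited table gives FPKM per locus and library as made by the authors, with 1 column per library. Reads were aligned with TopHat to the GRCm38 mouse genome, per the submitters' processing notes, and the versions, the quantification tool and the annotation are not given in the sources used here. The smallest value above 0 is 1.76e-261 FPKM, so the deposited FPKM values are model estimates that hold no whole-read steps, and the depth of the libraries is unknown. Coordinates are those of the deposited table, on GRCm38.

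The table holds 24157 loci. Of these, 21853 carry an Ensembl gene ID, 21545 of which (98.6%) were matched to a symbol, and 2304 are assembled loci without an Ensembl ID that are named by their locus number and the name in the table. Loci of the mitochondrial chromosome numbered 0, and 4427 loci are listed at 0 in all libraries. Groups and replicate numbers were taken from the sample titles, and all 9 columns were matched to samples by name. Where near-identical copies exist (C4a and C4b, class I genes, globins, ribosomal pseudogenes), reads may be shared and the values are uncertain.

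The authors' scaling was kept. Values were analysed as log2(FPKM + 1), a scale on which fold changes of low genes are understated, over the 12843 loci with a mean of at least 1 FPKM over the 9 libraries, 810 of them assembled loci. Group means were fitted in limma 3.58.1 (R 4.3.3) to all 9 libraries together, with an intensity trend in the empirical Bayes step and no covariates, and 3 contrasts were tested (old sham against young control, old hpMSC-treated against old sham, old hpMSC-treated against young control). Residual and prior degrees of freedom came to 10.5. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

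Gene lists for cell types, brain regions and pathways, 47 in all with 1002 entries, were written before the data were examined, together with the comparisons, the tests, the alternatives listed below up to cross-fitting and the rule for named genes. Entries were matched to loci with an Ensembl ID only, so assembled loci, such as those named for Clec7a and immunoglobulin kappa, are outside the lists. Of the entries, 903 were found in the table and 789 passed the filter. The 42 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with a correlation estimated per list. Members were also adjusted over the list alone. The lists MHC class II (3 of 7 members tested), T cells (1 of 12), B and plasma cells (1 of 11), mitochondrially encoded (0 of 26) and sex-linked genes (0 of 6) were too small to test. In each comparison the named genes are the 12 with the largest rise and the 12 with the largest fall among loci that passed and whose groups do not overlap, leaving out predicted genes, Rik clones, pseudogenes and loci with several symbols. Directions with fewer than 12 such loci were filled by the smallest unadjusted p among non-overlapping loci. Of each list described, up to 4 members with the smallest p were named, and members named for other reasons are said to have been chosen after their values were seen.

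The opposition of age and treatment differences was measured as the share of loci changed with age whose treatment difference has the opposite sign, and as the covariance of both log2 fold changes over all loci. Because the old sham libraries enter both, both were compared with 100 simulations that keep an age difference and hold no treatment effect, and computed again with separate old sham libraries for each difference (cross-fitted). The age difference kept in the simulations is that of the mean over both old groups from young control, not that of old sham alone. The simulated slope was added after the data were seen. Each alternative changed 1 choice. Alternatives were pseudocounts of 0.1 and 0.5, no filter and a minimum mean of 5 FPKM, median-of-ratios and quantile scaling, the replicate number as a block, leaving out each library, a fit on the 2 groups compared, empirical Bayes without a trend or robust, array weights, the estimated correlation, the 200 loci with the smallest p with age, and cross-fitting. Removing each library's trend over transcript length (lowess, span 0.3, on the 12011 tested loci with a known length, 93.5%) and using Ensembl loci only were added after the data were seen. Transcript length is that of the longest annotated transcript of each gene, which need not be the one expressed.

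The steps were tested on simulated data with 200 changed genes among 12843 in 20 simulations per contrast. For old sham against young control, 74.1% of genes changed 1.5-fold, 97.2% of those changed 2-fold and 99.6% of those changed 4-fold were recovered, and 4.9% of calls were false. For old hpMSC-treated against old sham the shares were 73.1%, 97.3% and 99.7%, with 4.7% of calls false. A shifted gene list was called in 100% of simulations and unshifted lists in 0.37%. The simulated genes varied independently of each other, so the 0.37% does not hold for lists whose members move together. The cross-fitted covariance averaged 4.4e-05 (SD 0.0027) in simulations without a treatment effect.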

Results

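RNA sequencing measured gene expression in hippocampal tissue of mice in 9 libraries, 3 each from young control, old sham and old hpMSC-treated animals. The title of the series expands hpMSC as human placenta-derived mesenchymal stem cells, and its design text names PBS as the treatment of aged mice that were not given the cells. Each library has model-estimated FPKM values at 24157 loci, of which 12843 had a mean of at least 1 FPKM and were tested. Read counts are not part of the values analysed here, so the depth of each library is unknown and no interval or detection limit that needs it is given. The sum of FPKM ran from 511834 in old hpMSC-treated 2 to 1084170 in young control 1, and 23.2% to 65.9% of it lay in loci of at most 500 bp. The labels do not say that the replicates are separate animals, so p-values measure the spread between these libraries, which may be technical.

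Spearman correlations across genes were 0.984 to 0.988 between libraries of the same group, 0.984 to 0.987 between old sham and old hpMSC-treated libraries and 0.980 to 0.984 between young control and old libraries. The first principal component held 40.6% of the variance. Young control libraries lay between -23.6 and -18.7 on it, old sham libraries between 9.16 and 18.4, and the old hpMSC-treated libraries at -3.15, 7.68 and 17.4 for replicates 1, 2 and 3. Expression relative to the gene's mean had Spearman correlations with transcript length of 0.26, -0.09 and 0.24 in young control 1, 2 and 3, of 0.01, -0.28 and -0.28 in old sham and of 0.30, 0.07 and -0.19 in old hpMSC-treated (across genes, which are not independent replicates). The 4 globin genes summed to 42.2 FPKM in old hpMSC-treated 1 and to 1.37 to 6.05 FPKM in the other libraries.

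The first comparison asked how the hippocampus of old sham mice differed from that of young controls. 11 of 17 astrocyte, 10 of 14 homeostatic microglia and 7 of 9 complement genes rose, and 10 of 16 endothelial, 9 of 17 thalamus and 10 of 18 dentate granule genes fell in old sham. Each of these 6 lists was called at a preset correlation and none with an estimated correlation (adjusted p = 0.52 for each). The labels give the sham procedure to old mice alone, so age and that procedure are confounded here, and "with age" below stands for old sham against young control. Gfap, the intermediate filament of astrocytes, rose from 105 ± 8.12 FPKM in young control to 335 ± 60.4 FPKM in old sham (SD, n = 3 each), a log2 fold change of 1.65 with a standard error of 0.21 (limma adjusted p = 0.00358). C4b, a complement component, rose from 4.73 ± 0.52 to 19.7 ± 5.65 FPKM (SD, n = 3 each; log2 fold change 1.82, standard error 0.18, limma adjusted p = 0.00188). Gpr17, a receptor of maturing oligodendrocyte precursors, fell from 13.2 ± 0.92 to 5.21 ± 0.35 FPKM (SD, n = 3 each; log2 fold change -1.19, standard error 0.09, limma adjusted p = 0.000436).

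**Figure D1:**
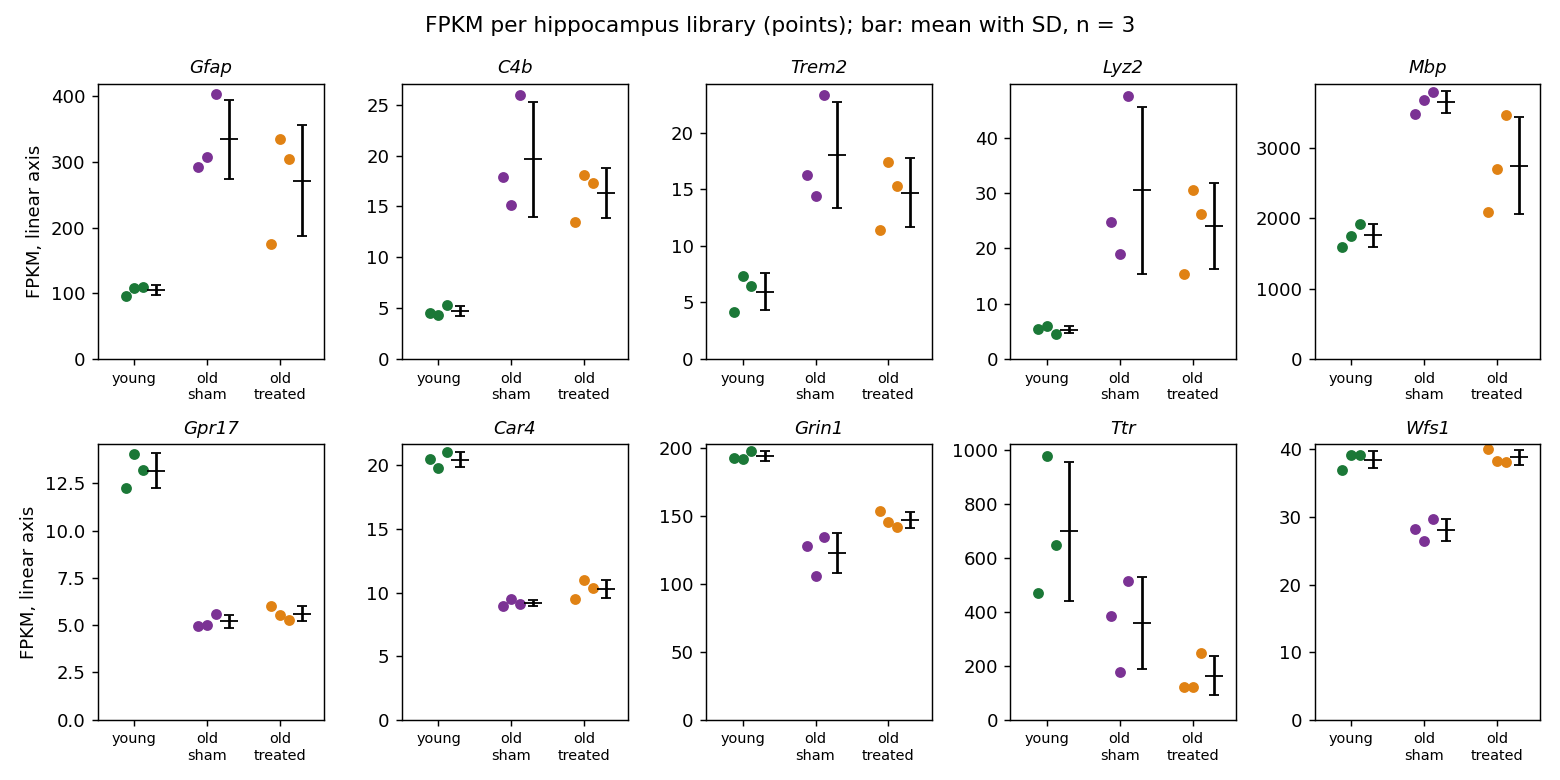
FPKM of 10 named genes on linear axes, with each library as a point and the group mean with its SD (n = 3) as a bar. Gfap, C4b, Trem2, Lyz2 and Mbp lie higher in all 3 old sham libraries than in all 3 young control libraries, Gpr17, Car4 and Grin1 lie lower, and the means of Ttr are 698, 359 and 164 FPKM in young control, old sham and old hpMSC-treated.

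In all, 3148 of 12843 loci changed between old sham and young control in limma, 1677 higher and 1471 lower in old sham, with a median absolute log2 fold change of 0.44. Of these, 72 changed more than 2-fold and 175 were assembled loci without an Ensembl gene. The libraries of both groups did not overlap at 5620 loci, or 43.8%, where chance gives 10%. Among the 12 largest rises, an assembled locus that the deposited file names Clec7a, the receptor dectin-1 of myeloid cells (XLOC_018134, chromosome 6, 129461368 to 129472793, GRCm38), had a log2 fold change of 2.34 (limma adjusted p = 0.00248). Lyz2, a lysozyme of myeloid cells, stood at 2.22. Below it and C4b and Gfap, given above, came Ifit3 at 1.49, Trem2, a lipid receptor of microglia, at 1.45, Cd52 at 1.37, S100b at 1.37, Mpeg1 at 1.34 and Ly86 at 1.31. An assembled retroviral gag-pol locus (XLOC_016161, chromosome 5, 133292091 to 133296988, GRCm38) rose by 1.57. The largest fitted rise, 2.87 with a standard error of 0.80, was at an assembled locus that the file names as an immunoglobulin kappa constant region (XLOC_017292, chromosome 6, 70722510 to 70726908, GRCm38). It held 0.44 ± 0.35 FPKM in young control and 19.6 ± 26.2 FPKM in old sham (SD, n = 3 each, limma adjusted p = 0.028), and it no longer passed without young control 1, 2 or 3 or old sham 2 (adjusted p = 0.0726, 0.0739, 0.0579 and 0.0682).

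Among the 12 largest falls were 2 assembled retroviral loci, gag-pol on chromosome 7 (XLOC_020363, 7073786 to 7074090, GRCm38) at -2.31 and pol on chromosome 18 (XLOC_010290, 30266226 to 30272363, GRCm38) at -1.75. Prkcd, a protein kinase C isoform, had a log2 fold change of -1.46, Synpo2 of -1.29, F5, coagulation factor V, of -1.25, Snhg11, a small nucleolar RNA host gene, of -1.24, and Rgs16 of -1.17. Kl, the klotho gene, stood at -1.13, Ly6c1, an endothelial surface antigen, at -1.09, Nptx2, a secreted pentraxin of excitatory synapses, at -1.08 and Car4, a carbonic anhydrase of brain capillaries, at -1.07. Car4 fell from 20.4 ± 0.60 to 9.19 ± 0.25 FPKM (SD, n = 3 each, limma adjusted p = 0.000436). All of these passed at an adjusted p under 0.05 and had no overlap between both groups' libraries.

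Of 42 gene lists tested with limma's camera at a preset correlation, 22 were called between old sham and young control, 12 higher and 10 lower. With a correlation estimated from the libraries 0 were called, 2 had an unadjusted p under 0.05, and the smallest adjusted p was 0.52. Homeostatic microglia markers were called higher (median log2 fold change 0.55, adjusted p = 2.77e-07), with 10 of 14 members rising and 13 adjusted over the list alone (adjusted p = 0.52 with an estimated correlation). Siglech rose by 0.90, P2ry12, a purine receptor of resting microglia, by 0.56 and Gpr34 by 1.02. Disease-associated microglia markers had a median of 0.72 (adjusted p = 0.000166), 9 of 16 rising and 12 adjusted over the list alone, among them Lyz2 and B2m, which rose by 0.81 (adjusted p = 0.52 with an estimated correlation). In the complement list, 7 of 9 members rose, 7 also adjusted over the list alone (adjusted p = 3.69e-05), C1qb by 1.12 and C1qa by 1.18 (adjusted p = 0.52 with an estimated correlation). C4b may share reads with its close copy C4a, which was not tested, so its value is uncertain. Astrocyte markers had a median of 0.53, with 11 of 17 rising, 12 adjusted over the list alone (adjusted p = 5.6e-06), and Slc1a3, a glutamate transporter, rose by 0.57 (adjusted p = 0.52 with an estimated correlation).

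Interferon response genes were called higher with age (median 0.43, adjusted p = 0.000348), with 7 of 15 rising and 1 falling, and 9 and 1 adjusted over the list alone (adjusted p = 0.52 with an estimated correlation). Ifit3 and Ifit1, which rose by 1.49 and 0.88, are interferon-induced, and the member that fell was Stat2 (-0.38), a signal transducer of type I interferon. Of 8 genes of MHC class I antigen presentation, B2m, Psmb8 and H2-K1 rose, 4 passed adjusted over the list alone, and the list had an adjusted p of 0.0146 (adjusted p = 0.52 with an estimated correlation). Psmb8, an immunoproteasome subunit, rose by 0.83, and reads of H2-K1 may be shared with other class I genes. Oligodendrocyte and myelin genes had a median of 0.26, with 7 of 22 rising and 2 falling, 9 and 3 adjusted over the list alone (adjusted p = 0.0482, and adjusted p = 0.69 with an estimated correlation). Mbp, myelin basic protein, rose from 1753 ± 159 to 3646 ± 151 FPKM (SD, n = 3 each; log2 fold change 1.06, limma adjusted p = 0.00739). Mobp rose by 1.29 and Apod by 1.13. The falling members Cldn11 (-0.57), the tight-junction claudin of myelin, and Tspan2 (-0.51) were named after their values were seen, as was Stat2. The myelin list lost its call without young control 1 or 2 or old sham 3 (adjusted p = 0.0845, 0.103 and 0.565) and with the transcript length trend removed (median 0.15, adjusted p = 0.0926). The same held with quantile normalization, a minimum mean of 5 FPKM or array weights (adjusted p = 0.106, 0.0634 and 0.0581). Mbp lost its call with quantile normalization (0.64, adjusted p = 0.141).

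Cytosolic ribosomal protein genes had a median log2 fold change of 0.54 with age, and 55 of 74 rose and 0 fell, 64 rising adjusted over the list alone (camera adjusted p = 7.53e-18, and adjusted p = 0.52 with an estimated correlation). Rpsa rose by 0.98 and Rps3a1 by 0.91, in values that may include reads of ribosomal pseudogenes. The longest annotated transcript per gene has a median of 1100 bases in the list, against 3500 over the tested loci with a known length. With each library's trend over that length removed, the median log2 fold change was 0.43. Antioxidant genes were called higher (median 0.22, adjusted p = 0.000623), with 9 of 24 rising, 9 adjusted over the list alone, among them Prdx1, a peroxiredoxin, by 0.98 and Nqo1, a quinone reductase, by 0.77 (adjusted p = 0.52 with an estimated correlation). Of 62 nuclear genes of oxidative phosphorylation, 12 rose and 1 fell, with the same counts adjusted over the list alone (median 0.21, adjusted p = 0.000179, and adjusted p = 0.69 with an estimated correlation). Ndufv2 of complex I rose by 0.55 and Uqcrc2 of complex III by 0.47, while Cox5a of complex IV fell by 0.33. In the proteasome list 8 of 32 rose and 1 fell, 9 and 1 adjusted over the list alone (median 0.15, adjusted p = 0.0197, and adjusted p = 0.69 with an estimated correlation), with Psmb3 at 0.43 and Psmc4 at -0.31. Cholesterol synthesis genes had a median of 0.16, with 5 of 21 rising and 1 falling, the same counts adjusted over the list alone (adjusted p = 0.0269, and adjusted p = 0.62 with an estimated correlation). Msmo1 rose by 0.65, Insig1 by 0.62, and Ebp, a sterol isomerase, fell by 0.70. Cox5a, Psmc4 and Ebp were named after their values were seen. The call of the oxidative phosphorylation list ended with the length trend removed (median 0.06, adjusted p = 0.162), as did that of the proteasome list (median 0.05, adjusted p = 0.322), which was also lost without young control 3 or old sham 2 (adjusted p = 0.113 and 0.0541) and with quantile normalization (adjusted p = 0.072). Cholesterol synthesis lost its call without old sham 1 (adjusted p = 0.182).

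Endothelial markers were called lower with age (median -0.50, adjusted p = 2.2e-06), 10 of 16 falling and 0 rising, 12 falling adjusted over the list alone (adjusted p = 0.52 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, had a log2 fold change of -0.60 and Pecam1 of -0.54. Pericyte and smooth muscle markers had a median of -0.38, 5 of 10 falling (Vtn, Cspg4, Tagln, Rgs5 and Acta2), and 7 falling and 1 rising adjusted over the list alone (adjusted p = 0.00484, and adjusted p = 0.52 with an estimated correlation). Vtn, vitronectin, stood at -0.68. Extracellular matrix genes had a median of -0.38, 8 of 21 falling and 1 rising, 13 and 1 adjusted over the list alone (adjusted p = 0.000623, and adjusted p = 0.52 with an estimated correlation). Tnc stood at -0.79 and Col4a1, a basement membrane collagen, at -0.61, while Sparc, a matrix glycoprotein, rose by 0.92. At a minimum mean of 5 FPKM the matrix list lost its call (adjusted p = 0.505). Thalamus and habenula markers had a median of -0.79, 9 of 17 falling and 15 adjusted over the list alone (adjusted p = 3.06e-06, and adjusted p = 0.52 with an estimated correlation). Beside Prkcd, Synpo2 and Rgs16, Plekhg1 fell from 14.8 ± 5.78 to 6.53 ± 0.43 FPKM (SD, n = 3 each). Their list median per library was 0.03, 0.53 and 1.00 in young control and between -0.40 and -0.16 in the old libraries. Choroid plexus markers had a median of -0.76, 7 of 19 falling and 13 adjusted over the list alone (adjusted p = 3.69e-05, and adjusted p = 0.54 with an estimated correlation). Slc4a5, a bicarbonate transporter of that epithelium, stood at -0.95 and lost its call without young control 2, young control 3 or old sham 2 (adjusted p = 0.0647, 0.0627 and 0.0516).

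Among neuronal lists, dentate granule markers had a median of -0.43 with age, 10 of 18 falling, also 10 adjusted over the list alone (adjusted p = 3.69e-05, and adjusted p = 0.52 with an estimated correlation). Prox1, the transcription factor of granule cells, had a log2 fold change of -0.91 and Trpc6 of -0.51. Glutamatergic synapse genes had a median of -0.26, 12 of 30 falling and 1 rising, 13 and 1 adjusted over the list alone (adjusted p = 7.19e-05, and adjusted p = 0.52 with an estimated correlation). Grin1, the obligatory NMDA receptor subunit, fell from 194 ± 3.51 to 123 ± 14.9 FPKM (SD, n = 3 each; log2 fold change -0.66, limma adjusted p = 0.00368). Grm1 stood at -0.94 and Nrgn at -0.48, while Shank1, a postsynaptic scaffold, rose by 0.61. GABAergic interneuron markers had a median of -0.12, 6 of 20 falling and 1 rising, the same counts adjusted over the list alone (adjusted p = 0.0284, and adjusted p = 0.54 with an estimated correlation). Npy stood at -0.76, Reln at -0.78 and Gad1, a GABA-synthesizing enzyme, at -0.56, while Pvalb, the parvalbumin gene, rose by 0.58. CA2 and CA3 pyramidal markers had a median of -0.09, 6 of 18 falling and 7 adjusted over the list alone (adjusted p = 0.0398, and adjusted p = 0.52 with an estimated correlation). Among them were Cpne4 at -0.58 and Prkcd, which is also on the thalamus list. Heat shock and unfolded protein genes had a median of -0.27, 6 of 18 falling and 1 rising, the same counts adjusted over the list alone (adjusted p = 0.000469, and adjusted p = 0.52 with an estimated correlation). Calr, a chaperone of the endoplasmic reticulum, stood at -0.81, Hyou1 at -0.69 and Hsp90ab1 at -0.67, while Hsp90aa1, the inducible form, rose by 0.49. Sparc, Shank1, Pvalb and Hsp90aa1 were named after their values were seen. Interneuron markers lost their call without young control 1, old sham 2 or old sham 3 (adjusted p = 0.0568, 0.0541 and 0.0565) and with the length trend removed, where the median was -0.13 (adjusted p = 0.058). CA2 and CA3 markers lost theirs without old sham 2 or old hpMSC-treated 3 (adjusted p = 0.0903 and 0.0513), in a fit on the 2 groups compared (0.0574) and at a minimum mean of 5 FPKM (0.0864).

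**Figure D2:**
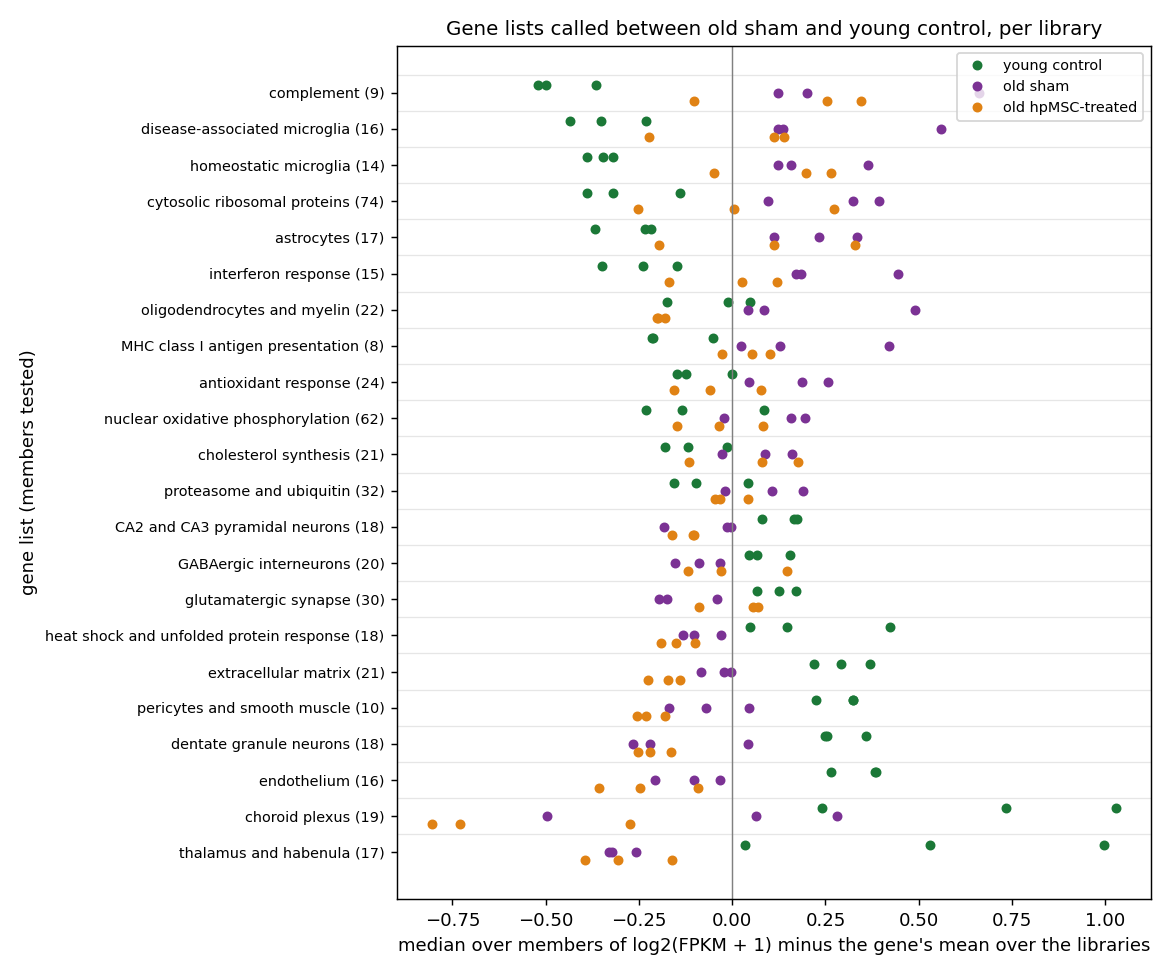
Median, per library, of log2(FPKM + 1) minus each gene's mean over the 9 libraries, for the 22 gene lists called between old sham and young control, with the number of members tested. Each point is a library. Thalamus markers spread from 0.03 to 1.00 over the young control libraries, and choroid plexus markers from 0.24 to 1.03.

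The number of loci changed with age fell from 3148 to 1744 without young control 1, to 1722 without young control 3 and to 1273 without old sham 2. Of the 79 named genes that passed, 65 passed without each library in turn. Besides the locus named for immunoglobulin kappa and Slc4a5, both given above, the exceptions were Cd52 (highest adjusted p = 0.0646, without young control 1), H2-K1 (0.11, without young control 1), Rgs5 (0.115, without old sham 2), Tagln (0.0777, without old sham 1) and Acta2 (0.127, without old sham 2). The other exceptions, members that ran against their list, were Pvalb (highest adjusted p = 0.0848, without young control 3), Shank1 (0.0863, without old sham 2), Stat2 (0.125, without old sham 2), Ebp (0.0515, without old sham 2), Cldn11 (0.0685, without young control 3), Tspan2 (0.0529, without old sham 2) and Psmc4 (0.0857, without young control 2). Calls were also lost by Acta2 with a pseudocount of 0.1 (adjusted p = 0.055), the locus named for immunoglobulin kappa with robust empirical Bayes (0.0649), and Stat2 and Psmc4 in a fit on the 2 groups compared (0.0502 and 0.0505). With no filter on low values, 6 of the 79 lost theirs. Among lists, choroid plexus markers had a median of -0.48 without old sham 2, interneuron markers of -0.20 without old sham 1, heat shock genes of -0.14 without young control 2, proteasome genes of 0.23 without young control 2 and myelin genes of 0.13 without old sham 3. CA2 and CA3 markers stood at -0.17 with the length trend removed and at -0.14, -0.13, -0.14 and -0.14 without young control 1 or 3 or old sham 1 or 3, oxidative phosphorylation genes at 0.13 with quantile normalization, and pericyte markers at -0.62 with a pseudocount of 0.1.

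The second comparison, which the design text names, set old hpMSC-treated against old sham libraries. Of 12843 loci, 0 passed in limma, 1207 had an unadjusted p under 0.05, and the smallest adjusted p was 0.484. The median standard error of a log2 fold change was 0.11, and the 95% interval reached a median of 0.24 to either side. The gene with the smallest p was Wfs1, the wolframin gene and a marker of CA1 pyramidal neurons, at 38.5 ± 1.25 FPKM in young control, 28.1 ± 1.62 in old sham and 38.8 ± 1.09 in old hpMSC-treated (SD, n = 3 each; log2 fold change of treatment 0.45, standard error 0.07, limma adjusted p = 0.484). Gpx3, a secreted glutathione peroxidase, stood at 4.67 ± 0.74 FPKM in young control, 5.86 ± 0.54 in old sham and 3.27 ± 0.05 in old hpMSC-treated, there below young control (SD, n = 3 each; log2 fold change of treatment -0.68, standard error 0.11, limma adjusted p = 0.484). The libraries of both groups did not overlap at 1833 loci, or 14.3%, where chance gives 10%.

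Since no gene passed, the 24 genes named for the treatment are those with the smallest unadjusted p among non-overlapping ones, and none of them changed by the test. Higher values in old hpMSC-treated than in old sham were found for Dpysl4 (log2 fold change 0.56), Necab1 (0.41), Osbp2 (0.38), Hrh3, the histamine H3 receptor (0.42), Camk2d (0.37), a locus named Shisa7 (XLOC_019313, 0.37), Unc13a, a synaptic vesicle priming factor (0.39), and Bmp3 (0.64). The same held for the gag-pol locus on chromosome 7 (XLOC_020363, 1.29), Plxnd1 (0.59) and Fbxl17 (0.34). Lower values were found for Gnpda2 (-0.39), Dnase2a, a lysosomal nuclease (-0.68), Ccdc153 (-0.85), Mtif3 (-0.54), Gstm6 (-0.41), Car13 (-0.62), Nqo1 (-0.68), Mcee (-0.45), Cd24a (-0.61), Aven (-0.40) and Osbpl9 (-0.32). Nqo1 had 4.14 ± 0.48, 7.75 ± 0.47 and 4.51 ± 1.11 FPKM in young control, old sham and old hpMSC-treated (SD, n = 3 each).

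Camera at the preset correlation called 20 of 42 lists between old hpMSC-treated and old sham, 12 lower and 8 higher, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05 and the smallest adjusted p was 0.38. In each list 0 members passed over all genes. Ribosomal protein genes were called lower (median -0.26, adjusted p = 4.16e-12), with 0 of 74 passing adjusted over the list alone (adjusted p = 0.55 with an estimated correlation). Rps23 stood at -0.33 and Rps6 at -0.39. With the length trend removed the median was -0.13, and it was -0.14 without old hpMSC-treated 1 and -0.39 without old hpMSC-treated 3. The per-library medians of this list were -0.25, 0.01 and 0.27 in old hpMSC-treated 1, 2 and 3 and 0.10, 0.40 and 0.32 in old sham 1, 2 and 3. Oligodendrocyte and myelin genes had a median of -0.37 (adjusted p = 3.6e-10), and 6 of 22 passed adjusted over the list alone (adjusted p = 0.51 with an estimated correlation). These were Ermn (-0.39), Aspa (-0.54), Gjb1 (-0.45), Car2 (-0.45), Qdpr (-0.41) and Il33 (-0.45). Antioxidant genes had a median of -0.20 (adjusted p = 3.71e-06), and Gpx3, Nqo1, Slc7a11 (-0.36) and Prdx1 (-0.36), 4 of 24, passed adjusted over the list alone (adjusted p = 0.51 with an estimated correlation). Ependymal markers had a median of -0.49 (adjusted p = 1.92e-05), and 5 of 9 passed adjusted over the list alone, Ccdc153, Dynlrb2 (-0.80), Foxj1, the regulator of motile cilia (-0.49), Tmem212 (-0.67) and Rarres2 (-0.52) (adjusted p = 0.51 with an estimated correlation). Qdpr and Rarres2 were named after their values were seen.

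Choroid plexus markers were lower still in the old hpMSC-treated libraries (median -0.59, adjusted p = 2.8e-07), with 0 of 19 passing adjusted over the list alone, Cldn2 at -0.72 and Enpp2, autotaxin, at -0.74 (adjusted p = 0.55 with an estimated correlation). The per-library medians of this list overlapped, at -0.73, -0.806 and -0.275 in old hpMSC-treated 1, 2 and 3 and at 0.065, -0.496 and 0.282 in old sham 1, 2 and 3. Meningeal and fibroblast markers had a median of -0.31 (adjusted p = 0.000679), and Igf2 (-0.62) and Bmp6 (-0.53), 2 of 14, passed adjusted over the list alone (adjusted p = 0.55 with an estimated correlation). The oxidative phosphorylation list had a median of -0.17 (adjusted p = 1.67e-05), 0 of 62 adjusted over the list alone, and Ndufv2 at -0.26 (adjusted p = 0.64 with an estimated correlation). It lost its call with the length trend removed (median -0.00, adjusted p = 0.504). Interferon genes had a median of -0.35 (adjusted p = 0.000831), 0 of 15 adjusted over the list alone, with Ifit3 at -0.54 and Ifi27 at -0.35 (adjusted p = 0.55 with an estimated correlation). The median was -0.20 with the length trend removed, -0.21 with array weights, -0.23 with no filter and -0.18 without old sham 3. Disease-associated microglia markers had a median of -0.24 (adjusted p = 0.00799), 1 of 16, Lgals3 (-0.93), passing adjusted over the list alone (adjusted p = 0.58 with an estimated correlation). Astrocyte markers stood at -0.13 (adjusted p = 0.0142), 0 of 17 adjusted over the list alone, with Sox9 at -0.35 and S100b at -0.49 (adjusted p = 0.64 with an estimated correlation). Histones stood at -0.18 (adjusted p = 0.0208), 0 of 15 adjusted over the list alone, H3f3a at -0.26 (adjusted p = 0.58 with an estimated correlation). The proteasome list stood at -0.11 (adjusted p = 0.0208), 0 of 32 adjusted over the list alone, Psmb5 at -0.23 (adjusted p = 0.71 with an estimated correlation).

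Glutamatergic synapse genes were called higher in old hpMSC-treated than in old sham (median 0.14, adjusted p = 3.88e-09), with 0 of 30 passing adjusted over the list alone (adjusted p = 0.38 with an estimated correlation). Syngap1 stood at 0.29, Syn1 at 0.29 and Grin1 at 0.26. Immediate early genes, induced by neuronal activity, had a median of 0.18 (adjusted p = 0.000152), 0 of 21 adjusted over the list alone, with Egr3 at 0.30 and Dusp1 at 0.32 (adjusted p = 0.51 with an estimated correlation). Glucocorticoid response genes had a median of 0.17 (adjusted p = 0.00246), 0 of 15 adjusted over the list alone, with Sgk1 at 0.52 and Cdkn1a at 0.63 (adjusted p = 0.55 with an estimated correlation). The per-library median of that list was 0.50 in old hpMSC-treated 3 and at most 0.15 in the other libraries, and without that library the list's median turned to -0.06. GABAergic interneuron markers had a median of 0.12 (adjusted p = 0.00445), 0 of 20 adjusted over the list alone, with Npy at 0.31 and Pvalb at -0.43 (adjusted p = 0.55 with an estimated correlation). Circadian clock genes had a median of 0.06 (adjusted p = 0.0132), 0 of 17 adjusted over the list alone, with Npas2 at 0.45 and Hlf at 0.25 (adjusted p = 0.38 with an estimated correlation). CA1 markers had a median of 0.04 (adjusted p = 0.014), and Wfs1 alone of 13 passed adjusted over the list alone, with Satb2 at 0.47 (adjusted p = 0.38 with an estimated correlation). Neocortex markers stood at 0.07 (adjusted p = 0.0175), 0 of 17 adjusted over the list alone, Tbr1 at 0.42 (adjusted p = 0.51 with an estimated correlation). Hypoxia and glycolysis genes stood at 0.04 (adjusted p = 0.0345), 0 of 24 adjusted over the list alone, Pfkp at 0.30 (adjusted p = 0.55 with an estimated correlation).

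Of the 20 lists called for the treatment, 9 were called without each library in turn. Astrocyte, histone, disease-associated microglia and interneuron lists lost their calls without old hpMSC-treated 1 (adjusted p = 0.855, 0.432, 0.405 and 0.3), and the interferon, neocortex, CA1 and glucocorticoid lists without old sham 3 (adjusted p = 0.0599, 0.108, 0.107 and 0.107). The proteasome, circadian and astrocyte lists lost theirs without old sham 2 (adjusted p = 0.421, 0.0665 and 0.203). Leaving out old sham 3 also ended the calls of the disease-associated microglia and histone lists (adjusted p = 0.315 and 0.232). Hypoxia and glycolysis genes lost theirs without old sham 1, old sham 3, old hpMSC-treated 1 or old hpMSC-treated 3 (adjusted p = 0.0859, 0.0568, 0.052 and 0.222). Proteasome genes also lost theirs without old hpMSC-treated 1 or 2 (adjusted p = 0.088 and 0.097), and CA1 markers without old hpMSC-treated 3 (adjusted p = 0.0573). The median of the circadian list turned to -0.01 without old sham 2 and to -0.04 without old hpMSC-treated 1. With the length trend removed, the histone and proteasome lists were not called, at medians of -0.09 and -0.02 (adjusted p = 0.217 and 0.904). Nor were the CA1, circadian and neocortex lists, whose medians were then larger, at 0.06, 0.08 and 0.13 (adjusted p = 0.0536, 0.063 and 0.0841). With array weights the interneuron, meningeal and neocortex lists (adjusted p = 0.0732 each), the astrocyte, histone and disease-associated microglia lists (0.206, 0.208 and 0.26) and the circadian, glucocorticoid and hypoxia lists (0.0886, 0.716 and 0.469) were not called. The medians of these last 3 lists were then -0.02, -0.04 and -0.03. Hypoxia and glycolysis genes were also not called at a minimum mean of 5 FPKM (adjusted p = 0.0601), nor proteasome genes with median-of-ratios scaling (adjusted p = 0.0562).

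The medians of other lists called for the treatment also moved by more than 1.5 times under some settings. Without old sham 3 they were -0.22 (myelin), -0.38 (choroid plexus), -0.13 (antioxidant), -0.06 (disease-associated microglia) and -0.07 (histones). Without old hpMSC-treated 1 they were -0.13 (antioxidant), -0.20 (meninges), -0.09 (oxidative phosphorylation), -0.09 (disease-associated microglia), -0.10 (histones), -0.04 (astrocytes), 0.03 (interneurons) and 0.09 (immediate early genes). Without old hpMSC-treated 3 they were -0.30 (antioxidant), -0.29 (astrocytes) and 0.21 (interneurons), without old sham 1 -0.24 (astrocytes) and without old sham 2 0.08 (immediate early genes). With the length trend removed, antioxidant genes stood at -0.12 and disease-associated microglia markers at -0.15, and ependymal markers stood at -0.27 with no filter and at -0.32 with array weights. Over all settings the medians ran from 0.01 to 0.12 (CA1), -0.04 to 0.10 (circadian), -0.03 to 0.10 (hypoxia), 0.02 to 0.13 (neocortex), -0.17 to -0.02 (proteasome) and -0.06 to 0.32 (glucocorticoid).

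The third comparison set old hpMSC-treated against young control libraries, in which age, the procedure and the cells are confounded. In old hpMSC-treated 9 of 14 homeostatic microglia, 6 of 9 complement and 7 of 17 astrocyte genes rose. There 16 of 19 choroid plexus, 10 of 16 endothelial, 13 of 21 matrix, 12 of 17 thalamus and 9 of 18 dentate granule genes fell. These lists were called at the preset correlation and none with an estimated one (smallest adjusted p = 0.36). C4b rose to 16.3 ± 2.46 FPKM from 4.73 ± 0.52 (SD, n = 3 each; log2 fold change 1.59, standard error 0.18, limma adjusted p = 0.00636). Ttr, the transthyretin gene of the choroid plexus, fell to 164 ± 72.1 FPKM from 698 ± 258 (SD, n = 3 each; log2 fold change -2.10, standard error 0.41, limma adjusted p = 0.0184). Calr fell to 88.5 ± 4.01 FPKM from 159 ± 17.7 (SD, n = 3 each; log2 fold change -0.83, standard error 0.09, limma adjusted p = 0.00545).

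Between old hpMSC-treated and young control, 1200 of 12843 loci changed in limma, 518 higher and 682 lower, and with median-of-ratios scaling 664 were higher and 562 lower. The median absolute log2 fold change was 0.48 and 56 loci changed more than 2-fold. The libraries of both groups did not overlap at 4423 loci, or 34.4%, where chance gives 10%. Large rises were those of Lyz2 (1.94), the locus named Clec7a (XLOC_018134, 1.69), Gfap (1.31), Mpeg1 (1.30), Trem2 (1.18), Vamp7 (1.16), the gag-pol locus on chromosome 5 (XLOC_016161, 1.15), Fcgr2b, an inhibitory Fc receptor (1.13), and Slc11a1, a metal transporter of phagocytes (1.13). Acp7, named Papl in the file (1.10), and Slc25a34 (1.06) completed the 12. Large falls were those of the pol locus on chromosome 18 (XLOC_010290, -1.84), Kl (-1.73), F5 (-1.71), Folr1 (-1.62), Cldn2 (-1.61), Snhg11 (-1.60), Defb11 (-1.54), Enpp2 (-1.52), Slc4a5 (-1.46), Kcnj13 (-1.44) and Aqp1, a water channel (-1.40).

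Camera at the preset correlation called 19 of 42 lists between old hpMSC-treated and young control, 8 higher and 11 lower, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05 and the smallest adjusted p was 0.36. Homeostatic microglia markers had a median of 0.49, 9 of 14 rising and 13 adjusted over the list alone (adjusted p = 1.77e-09, and adjusted p = 0.36 with an estimated correlation). Gpr34 stood at 1.01 and Siglech at 0.65. Complement genes had a median of 0.58, 6 of 9 rising, and 7 rising and 1 falling adjusted over the list alone (adjusted p = 5.02e-05, and adjusted p = 0.45 with an estimated correlation), with C1qb at 0.95. Astrocyte markers had a median of 0.29, 7 of 17 rising and 8 adjusted over the list alone (adjusted p = 2.68e-05, and adjusted p = 0.48 with an estimated correlation), with Slc1a2 at 0.69. Of 16 disease-associated microglia markers, Lyz2 and Axl (0.72) rose, 6 adjusted over the list alone (median 0.38, adjusted p = 0.00412, and adjusted p = 0.48 with an estimated correlation). Interferon genes had a median of 0.30, Ifit3 rising by 0.95 and Stat2 at -0.42 among 15, 3 and 1 adjusted over the list alone (adjusted p = 0.0182, and adjusted p = 0.48 with an estimated correlation). Ribosomal protein genes had a median of 0.28, and Rpsa, which rose by 0.64, was the 1 of 74 that passed, also adjusted over the list alone (adjusted p = 7.75e-11, and adjusted p = 0.48 with an estimated correlation). Of 21 cholesterol synthesis genes Stard4 (0.46), Insig1 (0.48) and Msmo1 (0.46) rose and Ebp (-0.89) fell, 4 and 1 adjusted over the list alone (median 0.13, adjusted p = 0.00457, and adjusted p = 0.48 with an estimated correlation). Of 9 protocadherin genes Pcdhb2 (0.70) and Pcdhb8 (0.61) rose, 3 adjusted over the list alone (median 0.26, adjusted p = 0.0199, and adjusted p = 0.48 with an estimated correlation).

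Choroid plexus markers had a median of -1.34 in old hpMSC-treated against young control, 16 of 19 falling and all 19 adjusted over the list alone (adjusted p = 8.26e-12, and adjusted p = 0.45 with an estimated correlation). Endothelial markers had a median of -0.64, 10 of 16 falling and 14 adjusted over the list alone (adjusted p = 1.07e-08, and adjusted p = 0.36 with an estimated correlation). Slco1a4 stood at -0.88, Cdh5 at -0.68 and Tek at -0.82. Matrix genes had a median of -0.54, 13 of 21 falling, and 14 falling and 1 rising adjusted over the list alone (adjusted p = 3.55e-06, and adjusted p = 0.36 with an estimated correlation), with Plod1 at -0.67 and Bgn at -0.95. Their call was lost at a minimum mean of 5 FPKM (adjusted p = 0.193). Pericyte markers had a median of -0.60, 6 of 10 falling, and 7 falling and 1 rising adjusted over the list alone (adjusted p = 0.000314, and adjusted p = 0.36 with an estimated correlation). Vtn stood at -1.02, Rgs5 at -0.57 and Acta2 at -0.98. Of 14 meningeal markers, Igf2 (-1.30), Slc13a4 (-1.09), Col1a2 (-0.82) and Aebp1 (-0.57) fell, 10 adjusted over the list alone (median -0.56, adjusted p = 4.89e-05, and adjusted p = 0.45 with an estimated correlation). Of 9 ependymal markers, Dynlrb2 (-0.93), Tmem212 (-0.81) and Ccdc153 (-0.62) fell, 5 adjusted over the list alone (median -0.41, adjusted p = 0.00412, and adjusted p = 0.48 with an estimated correlation). Thalamus markers had a median of -0.86, 12 of 17 falling and 14 adjusted over the list alone (adjusted p = 1.95e-07, and adjusted p = 0.45 with an estimated correlation), with Rgs16 at -1.21, Prkcd at -1.20 and Synpo2 at -1.17.

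Dentate granule markers had a median of -0.44 in the same comparison, 9 of 18 falling and 11 adjusted over the list alone (adjusted p = 2.68e-05, and adjusted p = 0.45 with an estimated correlation), with Prox1 at -1.04 and C1ql2 at -1.24. Of 18 CA2 and CA3 markers, Grik4 (-0.59), Prkcd, Amigo2 (-0.51) and Cpne4 (-0.39) fell, 8 adjusted over the list alone (median -0.23, adjusted p = 0.0323, and adjusted p = 0.48 with an estimated correlation). Heat shock and unfolded protein genes had a median of -0.40, 7 of 18 falling, and 10 falling and 1 rising adjusted over the list alone (adjusted p = 3.87e-05, and adjusted p = 0.45 with an estimated correlation), with Hyou1 at -0.62. Of 14 oligodendrocyte precursor markers Gpr17 (-1.10) and Cspg4 (-0.63) fell, 2 falling and 1 rising adjusted over the list alone (median -0.32, adjusted p = 0.0483, and adjusted p = 0.45 with an estimated correlation). That list lost its call without young control 3, old sham 1 or old hpMSC-treated 1 (adjusted p = 0.168, 0.0504 and 0.16). It also lost it with the replicate number as a block (0.0578), a pseudocount of 0.1 (0.051), a minimum mean of 5 FPKM (0.216) and array weights (0.0964). The CA2 and CA3 list lost its call without old hpMSC-treated 1 (adjusted p = 0.104), at a minimum mean of 5 FPKM (0.0645) and with array weights (0.0748), and the protocadherin list without old hpMSC-treated 1 (adjusted p = 0.126).

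The number of loci changed between old hpMSC-treated and young control was 449, 166 and 149 without young control 1, 2 and 3, and 1975, 75 and 201 without old hpMSC-treated 1, 2 and 3. Of the 65 named genes that passed, 19 passed without each library in turn, among them C4b, Mpeg1, Gpr34, Siglech, Calr, Gpr17, Vtn, Kl, Igf2 and Prox1. Ttr, Lyz2, Gfap and Trem2 were among the others (adjusted p = 0.0752, 0.0514, 0.0514 and 0.0645 without old hpMSC-treated 2). Calls were also lost by Stat2 with the replicate block or quantile normalization (adjusted p = 0.0593 and 0.0621) and by Ccdc153 in a fit on the 2 groups compared (0.06). Cpne4 lost its call with a pseudocount of 0.1, median-of-ratios scaling or no intensity trend (adjusted p = 0.0504, 0.0644 and 0.0644), and 16 of the 65 lost theirs with no filter on low values. Among lists, interferon genes had a median of 0.16 and ribosomal protein genes of 0.15 without old hpMSC-treated 3, and astrocyte markers had one of 0.49 without old hpMSC-treated 1. Cholesterol synthesis genes stood at 0.07 and 0.22 without old hpMSC-treated 2 and 3 and at 0.25 with array weights, and heat shock genes at -0.26 without young control 2. With no filter, interferon genes stood at 0.18 and pericyte markers at -0.28, and at a minimum mean of 5 FPKM complement genes stood at 0.89 and matrix genes at -0.15. Of the 1200 loci, 464 were also higher and 532 also lower in old sham than in young control, 204 had not passed there and 0 had passed in the opposite direction. Independent lists of these sizes would share 67.6 and 78.1 loci. The same young controls enter both comparisons, and their part in the excess was not tested.

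The title of the series speaks of an attenuation of ageing profiles, and the fourth comparison asked whether treatment differences ran opposite to age differences. Of the 3148 loci that changed with age, 86.9% had a treatment difference of the opposite sign, 91.2% of those raised and 82.0% of those lowered. Among them were Gfap (1.65 with age, -0.34 with treatment), S100b (1.37 and -0.49), Mbp (1.06 and -0.44), Nqo1 (0.77 and -0.68), Nptx2 (-1.08 and 0.65) and Grin1 (-0.66 and 0.26). Without old hpMSC-treated 1 the treatment difference of Gfap was -0.05 and that of Mbp -0.26. Kl (-1.13 and -0.60), F5 (-1.25 and -0.46) and Slc4a5 (-0.95 and -0.51), markers of the choroid plexus, had treatment differences of the same sign as age. None of these 9 genes passed for the treatment. The list calls that follow are at the preset correlation, and with an estimated one camera called 0 lists for age and 0 for the treatment (smallest adjusted p = 0.52 and 0.38). Of the 12 lists called higher with age, camera called 8 lower for the treatment and none higher, and the other 4 had medians of -0.21 (MHC class I), -0.17 (complement), -0.11 (homeostatic microglia) and -0.04 (cholesterol synthesis). Of the 10 called lower with age, glutamatergic synapse genes (0.14) and interneuron markers (0.12) were called higher and choroid plexus markers (-0.59) lower (camera adjusted p = 0.38, 0.55 and 0.55 with an estimated correlation). The other 7, not called for the treatment, had medians of -0.19 (pericytes), -0.14 (matrix), -0.07 (endothelium), -0.06 (dentate granule), -0.06 (heat shock), -0.04 (CA2 and CA3) and -0.04 (thalamus), beside a median of -0.04 over all loci. With the length trend removed, CA2 and CA3, thalamus and heat shock genes had medians of 0.01, 0.03 and 0.02, and the matrix list was called lower (median -0.15, adjusted p = 0.00808). The least-squares slope of treatment on age difference over these loci was -0.27. The old sham libraries enter both differences with opposite signs, so the share lies above chance and the slope below 0 with no treatment effect. The medians of lists called with age are pushed the opposite way for the treatment in the same manner, and no simulated value was made for the lists. In 100 simulations without a treatment effect, all old libraries were given the mean over both old groups, so the age difference there is not that of old sham alone. The share then averaged 62.5% (95% of them between 60.9% and 64.1%) and the slope -0.09 (95% between -0.15 and -0.06). The simulated libraries vary independently, without structure shared between libraries. Other assignments of the 6 old libraries to the roles of old sham and old hpMSC-treated gave shares from 29.8% to 92.5% and covariances from -0.0421 to 0.00166.

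**Figure D3:**
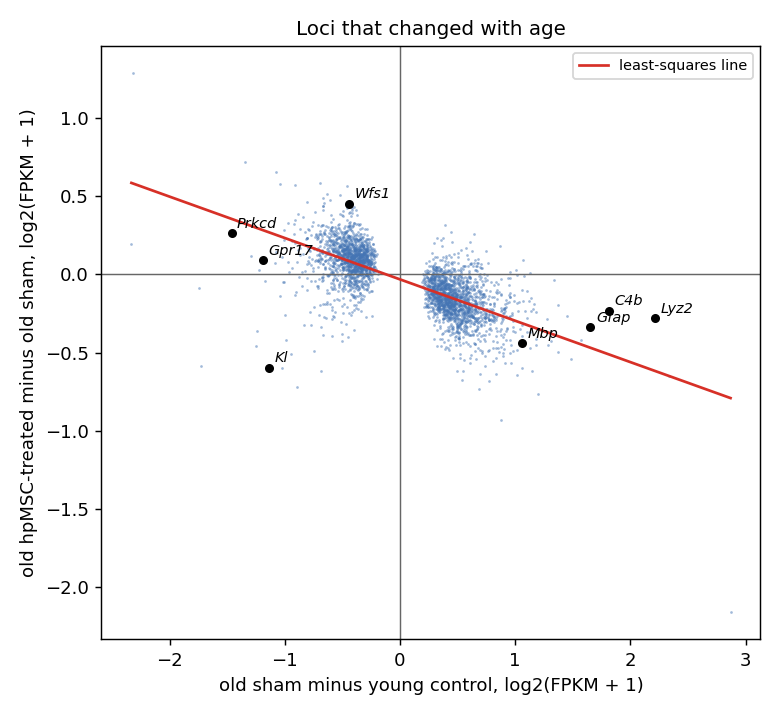
Log2 difference of old hpMSC-treated from old sham against that of old sham from young control for the 3148 loci that changed with age, each a point, with a least-squares line of slope -0.27 and 8 named genes in black. Loci raised with age lie mostly below 0 and loci lowered with age mostly above it, with Kl among the exceptions.

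Across all 12843 loci the age and treatment differences had a Pearson correlation of -0.49 and a covariance of -0.0297, across genes that are not independent replicates. In simulations with neither an age nor a treatment effect the correlation was -0.50. That value is no match for the observed one, since the real libraries hold age differences that those simulations lack. The simulated covariance without a treatment effect was -0.00983 (95% of simulations from -0.0144 to -0.00617), a difference of -0.0198. When the age difference was taken from 1 old sham library and the treatment difference from the other 2, so that no library entered both, the covariance averaged -0.0143 over the 3 choices (SD 0.00379), the correlation -0.19 and the share of opposite signs 76.2%. The loci of the cross-fitted share were chosen anew from that 1 old sham library and the young controls, so it is not over the same loci as the main share. Without old hpMSC-treated 1 the share was 72.2% and the covariance -0.0186, and the cross-fitted values were 60.0% and -0.00317 (SD 0.00579 over the 3 choices).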

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

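The alternatives that remove the length trend or keep Ensembl loci only were chosen after the data were seen. Of the 22, 20 and 19 lists called for age, treatment and old hpMSC-treated against young control, 15, 7 and 15 were called under each of 22 settings (the estimated correlation not among them). Of the 79 and 65 genes named in the report that passed for age and for old hpMSC-treated against young control, 64 and 19 passed under each, and of the 73 genes named there for the treatment 41 passed with array weights and none under another setting. With a correlation estimated per list, 0, 0 and 0 lists were called. Array weights gave 305 loci and 11 lists for the treatment, 5222 loci for old hpMSC-treated against young control and a share of opposite signs of 80.7%, with a weight of 19.6 on old hpMSC-treated 2 from a weight estimate that did not converge, and the cause was not tested. Without a filter 664 loci differed between old hpMSC-treated and young control, and at a minimum mean of 5 FPKM 11 lists did (fewer members tested). A pseudocount of 0.1 moved the covariance to -0.0418, and the cause was not tested. The share was 94.0% among the 200 loci with the smallest p with age and 76.2% when cross-fitted, where the covariance was -0.0143 (no library enters both differences, and the loci of the share are chosen anew). Leaving out each library in turn gave 1273 to 3466 loci and 21 to 23 lists for age, 0 to 0 loci and 14 to 22 lists for the treatment, 75 to 1975 loci and 18 to 24 lists for old hpMSC-treated against young control, a share of 72.2% to 91.8% and a covariance of -0.0442 (without old sham 1) to -0.0186 (without old hpMSC-treated 1), beside -0.0397 without old hpMSC-treated 3. Fewer libraries per group contribute to the lower counts. The glucocorticoid list, at 0.17, reversed to -0.057 without old hpMSC-treated 3, the library with its highest median, and ran up to 0.318 without old sham 2. Between old hpMSC-treated and young control, 43.2% of calls were higher, against 54.2% with median-of-ratios scaling, 52.3% with quantile normalization and 53.7% with the length trend removed. Removing that trend gave 3288, 0 and 1619 loci for age, treatment and old hpMSC-treated against young control, and Ensembl loci alone gave 3014, 0 and 1197. The labels do not say what libraries of the same number share, and whether the numbers pair the samples stays open. Deviations of same-numbered libraries correlated at -0.0494 to 0.186 and those of differently numbered ones at -0.182 to 0.161. The 3 of 9 same-numbered pairs over 0.1 were those of replicate 1 (0.111, 0.164 and 0.186). With the replicate block, 3471, 0 and 1429 loci and 23, 21 and 18 lists were called. What depth limits cannot be read from FPKM values, and the fold changes of low loci are understated by the pseudocount.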

Other observations

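The tests of the dissection share and of the transcript length trend in ribosomal protein genes, and the splits of the libraries, were chosen after the results were seen. Among the 20 lists that camera did not call between old sham and young control, 7 of 25 autophagy and lysosome genes rose and 2 fell (median 0.19, adjusted p = 0.109). Ctss, the lysosomal protease cathepsin S, rose from 32.9 ± 4.15 to 82.3 ± 18.8 FPKM (SD, n = 3 each; log2 fold change 1.28, limma adjusted p = 0.00376), Hexb rose by 0.57 and Lamp2, a lysosomal membrane protein, by 0.46, while Psap, the precursor of saposins, fell by 0.33. Of 14 oligodendrocyte precursor markers Bcas1 rose by 1.06 and 4 fell, among them Gpr17, Cspg4 (-0.62) and Tnr (-0.62) (median -0.24, adjusted p = 0.109). Of 7 inflammatory cytokine and chemokine genes Il18 (0.69), Casp1, the protease that activates interleukins 1 beta and 18 (0.65), and Tgfb1 (0.50) rose and Cxcl12 (-0.57) fell (median 0.40, adjusted p = 0.133). Of 12 reactive astrocyte genes Gfap and Ggta1 (0.68) rose and Amigo2 (-0.45) fell (median 0.23, adjusted p = 0.205). Hgf (0.62) and Vegfb (0.62) were 2 of 3 growth factor genes that rose among 18, where 5 fell, among them Ntrk3, the receptor of neurotrophin 3 (-0.51; median -0.20, adjusted p = 0.205). Of 21 immediate early genes Egr3 (-0.60) and Jun (-0.58) fell (median -0.12, adjusted p = 0.223). Cd74 and H2-Aa, 2 of the 3 tested genes of the MHC class II list, rose by 0.96 and 0.70, with Cd74 at 1.11 ± 0.14, 3.13 ± 0.72 and 1.93 ± 0.61 FPKM in young control, old sham and old hpMSC-treated (SD, n = 3 each), and H2-DMa stood at 0.26 (adjusted p = 0.166). Psap was named after its values were seen. Of these genes Psap, Tnr, Casp1, Tgfb1, H2-Aa and Amigo2 lost their calls in at least 1 fit without a library (highest adjusted p = 0.117, 0.0848, 0.0582, 0.134, 0.0901 and 0.103).

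Myelin genes went both ways between old hpMSC-treated and young control, where their list was not called (median -0.14, adjusted p = 0.345). Of its 22 members Mobp (0.84), Apod (0.76) and Hapln2 (0.59) rose, and Cldn11 (-0.84), Mag, the myelin-associated glycoprotein (-0.81), Tspan2 (-0.81), Mal (-0.69) and Fa2h, a fatty acid hydroxylase of myelin lipids (-0.53), fell. Tspan2 alone of these 8 passed without each library in turn, and the highest adjusted p of the other 7 came to between 0.0594 (Cldn11) and 0.133 (Fa2h). Hypoxia and glycolysis genes, 8 of 24 falling and 1 rising with age, were not called (median -0.11, camera adjusted p = 0.133). With the length trend removed they were called lower (median -0.18, camera adjusted p = 0.0343), and their calls under other settings were not followed. Striatum markers, 0 of 12 changing with age, had per-library medians from -0.76 in old sham 2 to 0.70 in old hpMSC-treated 3. The 5 blood genes tested had a median of 2.19 in old hpMSC-treated 1. Cd4, the tested member of the T cell list, stood at 1.12 ± 0.77, 1.64 ± 1.41 and 1.85 ± 1.52 FPKM in young control, old sham and old hpMSC-treated, and Ighg2c, that of the B and plasma cell list, at 1.04 ± 0.30, 1.42 ± 0.23 and 1.58 ± 0.17 (SD, n = 3 each, both with limma adjusted p over 0.05 in each comparison). The assembled locus named for immunoglobulin kappa, which had the largest fitted rise with age, has no Ensembl ID and is not counted in that list. Of the Y-linked genes, Ddx3y and Eif2s3y are listed at 0 in all 9 libraries, and Uty and Kdm5d reach at most 0.0789 and 0.0321 FPKM. No gene of the mitochondrial chromosome is in the values used here.

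Treatment differences ran opposite to age differences at 86.9% of the loci that changed with age. The old sham libraries shared by both differences cannot be excluded as the whole cause. With no library in both, the cross-fitted covariance was -0.0143 (SD 0.00379 over 3 choices of old sham library). The 3 choices reuse the young control and old hpMSC-treated libraries, so this SD is no sampling error. Over 20 assignments of the old libraries to the roles of old sham and old hpMSC-treated, it ran from -0.0272 to 0.0153. Of these 20, the real one among them, 4 were at least as negative as -0.0143. With the length trend removed the cross-fitted covariance was -0.0118 (SD 0.00501), so most of it was left without that trend. Without old hpMSC-treated 1 the cross-fitted covariance was -0.00317 (SD 0.00579 over the 3 choices), so that this library may be the source of much of the pattern. Without old hpMSC-treated 2 or 3 it was -0.0156 (SD 0.00389) and -0.0242 (SD 0.003). An effect of the treatment stays open and was not tested apart from these libraries, and the age difference also carries the sham procedure.

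Thalamus and choroid plexus markers were lower in old sham than in young control, by a median of 0.79 and 0.76. A length trend is argued against, since 107% and 101% of these medians were left with it removed. A different share of thalamus and choroid plexus in the dissected pieces stays a hypothesis. The members of each list moved together within groups (mean correlations of 0.595 and 0.788, against 95th percentiles of 0.1 and 0.101 for matched random lists). For each, 0 of 10000 such lists were as high, where 1e-04 is the smallest share above 0 that they can give. The list medians of the 3 young control libraries spanned 0.964 (thalamus) and 0.785 (choroid plexus). Over the old sham libraries they spanned 0.0726 and 0.777, so the thalamus markers had little spread there. Markers of 1 tissue may move together for other reasons, and no other marker list was put through this test, so it cannot single out the dissection. Of 19 thalamus and 22 choroid plexus genes, 17 and 19 have a mean of at least 1 FPKM here and Prkcd is also on the CA2 and CA3 list, with Ttr at 698, 359 and 164 FPKM and Prkcd at 73.9, 24.6 and 29.5 FPKM in young control, old sham and old hpMSC-treated. Age and the sham procedure, which the labels give to old mice alone, are confounded here and stay open, as neither was tested apart from the dissection.

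Ribosomal protein genes were higher in old sham than in young control, by a median of 0.54. The length trend is argued against as the whole cause, since 78.7% of the median was left with the trend removed, and random lists matched in transcript length had a median of 0.15. The lengths used are those of the longest annotated transcript of each gene, so a trend over the transcripts expressed may be left in part. A single old sham library is argued against as well, since the highest camera adjusted p without each of them in turn was 1.56e-15 (adjusted p = 0.52 with an estimated correlation and all libraries). Age and the sham procedure, which are confounded, stay open and untested, and reads shared with pseudogenes were not tested.

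The 6 libraries of 2 groups can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For age, 1 of the 10 splits gave at least the real 3148 loci (highest other 0) and 2 gave at least the real 22 lists (highest other 24). For the treatment, 10 gave at least the real 0 loci (highest other 0; 1207 had an unadjusted p under 0.05 in the real split) and 3 at least the real 20 lists (highest other 22). For old hpMSC-treated against young control, 1 gave at least the real 1200 loci (highest other 0) and 2 at least the real 19 lists (highest other 21). The 6 old libraries can be put into the roles of old sham and old hpMSC-treated in 20 ways, again too few for a share under 0.05. Of these, 5 gave a share of opposite signs of at least the real 86.9% (highest other 92.5%), 4 a covariance at least as negative as the real -0.0297 (other extreme -0.0421), and 4 a cross-fitted covariance at least as negative as the real -0.0143 (other extreme -0.0272).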
